A study of Caenorhabditis elegans with 4 samples.

How the data were processed

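Binding of ELT-3, a GATA-type zinc finger transcription factor of the worm hypodermis (the epidermis under the cuticle), was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in fed first-stage (L1) Caenorhabditis elegans larvae. Per the labels, hermaphrodites of strain OP75 carried an integrated elt-3 transgene tagged with EGFP and FLAG, together with an unc-119 rescue gene. They were grown at 20 °C on bacteria in liquid medium and cross-linked with 2% formaldehyde, and the chromatin was sonicated and precipitated with an affinity-purified goat antiserum against GFP, per the labels' protocols, whose text on lysis speaks of embryos although the stage label is fed L1. The series holds 4 libraries, namely 2 ChIP libraries and 2 input DNA libraries, with 1 of each kind for each of 2 replicates.

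The data are 1 list of 5338 peaks for the whole series. The authors deposited for each peak a chromosome, a start, an end and a q-value (a p-value adjusted for multiple testing), and per the file headers the positions refer to the WormBase WS180 genome build. Every line of the deposited list names PeakSeq, a peak caller that compares ChIP with input, as its source. The attribute and the score column of the list hold the same q-value for every peak (0 peaks differed by more than a relative 1e-12). The other deposited values are positions in bp, counted from 1. The list is named as combined, but whether reads were pooled before calling or calls from the replicates were merged is not given in the sources used here, nor are the aligner, the fragment length, the filters or the software versions. No value per library is given in the list, so the read depth is unknown, no spread between replicates can be computed, and the intervals and p-values below describe the spread over peaks or stretches of the genome within this list. They do not describe how far a repeat of the experiment would differ. The q-values were used only to rank and filter peaks within the list.

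Width was computed as end minus start plus 1, and the position of a peak as its midpoint. The header gives no chromosome lengths and no genome of the build was used, so the last peak end of each chromosome stood in for its length. All peaks lay on the 6 nuclear chromosomes. The number of peaks on X was compared with its share of the summed length by a two-sided exact binomial test, with a permutation of 100 kb blocks between chromosomes (10000 draws) beside it, because neighbouring peaks are not independent. Peaks in the central part of the chromosomes, meaning the middle 33.3% of the length, were compared with 33.3% by an exact binomial test, with a 95% bootstrap interval over 100 kb blocks drawn within each part. Exact binomial (Clopper-Pearson) intervals at 95% are given for shares and order-statistic intervals for medians. Clustering was measured as the share of peaks with another peak midpoint within 2000 bp, against 1000 random placements without overlap that kept the number and widths of the peaks on each chromosome (one-sided permutation test). The relation of q-value to width was measured across peaks by Spearman's and Pearson's coefficients with 100000 permutations. Peaks are not independent replicates.

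The named peaks were chosen by a rule fixed before the data were examined, along with these tests and most alternatives. The rule took the 10 strongest peaks by q-value, the strongest peak of each chromosome, the 3 widest peaks and the 20 kb stretch with the most peaks. Alternatives were the stronger part of the list, peaks within 500 bp merged into 1, other distances and central parts, and each chromosome left out in turn. Tests of peak width and of very narrow peaks between chromosomes, of the strength of peaks with neighbours, of the difference in central share between X and autosomes, and permutations of 1 Mb blocks were added after seeing the data, as were placements with 200 bp gaps or within 1 Mb windows, lengths taken from the first to the last peak, and Pearson's coefficient without the 100 strongest peaks. Family-wide adjustment used the Benjamini-Hochberg method over the 6 chromosomes.

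Another 3 planned comparisons, namely peak position relative to genes, gene lists by tissue and the GATA sequence motif, were not run. The gene table at hand refers to the WBcel235 assembly, and positions from different builds were not mixed. No peak is therefore assigned to a gene here, including elt-3 and unc-119, the genes carried on the transgene.

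The tests of X density, of the central share, of clustering, of width on X and of neighbour strength were checked on simulated lists of 5338 peaks, 20 with built-in effects and 20 without. The other tests were not checked in this way. With effects, each of these 5 tests called 20 of 20 lists. Without effects, at most 2 of 20 lists were called by any of them. The peaks of the lists without effects were placed at random, without clustering. X density and the central share were scored by the exact binomial test alone. These counts thus do not show how often the tests would call lists of clustered peaks, such as the deposited one, without an effect. Nor do they show how often smaller effects would be called, since each built-in effect had a fixed size. The checks also drew fewer placements and permutations than the tests of the deposited list. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.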

Results

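The experiment asked where in the genome the transcription factor ELT-3 binds in fed L1 larvae of C. elegans. The 4 libraries formed 2 groups, with 2 ChIP libraries from precipitation of the ELT-3::GFP fusion protein and 2 input libraries of the same strain. The comparison of ChIP with input was made by the authors and is present as 1 combined list of peaks with q-values, without values per replicate. All positions below are in WormBase WS180 coordinates, and the peaks were not assigned to genes.

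ELT-3 binding was called at 5338 places, which together covered 3014.5 kb or 3.01% of the 100.2 Mb spanned by the 6 chromosomes. The median peak was 424 bp wide (95% interval 417 to 430 bp), and the central 50% of the peaks lay between 322 and 633 bp. Widths ran from 1 bp to 8584 bp, with 123 peaks wider than 2 kb and 22 wider than 4 kb. The q-values ran from 1.91e-228 to 0.00999, with a median of 7.72e-06. A q-value below 1e-05 was held by 2731 peaks, below 1e-20 by 494 peaks and below 1e-100 by 15 peaks.

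The strongest peak of the list lay near the middle of chromosome IV, at 8527218 to 8531667, with a width of 4450 bp and a q-value of 1.91e-228. Next came 2 peaks near opposite ends of X, at 1503387 to 1505307 (1921 bp, q-value 1.13e-209) and at 16929159 to 16932541 (3383 bp, q-value 3.88e-200). Chromosome I held the peaks ranked 4 and 5, at 7079154 to 7087737 with a q-value of 6.61e-192 and at 7656513 to 7660667 with a q-value of 2.40e-186. On chromosome II, the peaks at 7341643 to 7349357 (q-value 2.01e-179) and at 8818158 to 8821617 (q-value 3.52e-174) ranked 6 and 7. Another 2 peaks on X, at 15075620 to 15079896 (q-value 1.06e-158) and at 13935868 to 13940681 (q-value 1.16e-147), ranked 8 and 9. The peak ranked 10 was the strongest of chromosome V, at 8038970 to 8041781 with a q-value of 2.42e-126. The strongest peak of chromosome III ranked only 20, at 9050803 to 9055007 with a width of 4205 bp and a q-value of 1.75e-88. X thus held 4 of the 10 strongest peaks, chromosomes I and II held 2 each, and IV and V held 1 each. These 10 peaks were between 1921 and 8584 bp wide, all above the 95th percentile of the list, which was 1316 bp.

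The 3 widest peaks were the peak ranked 4 on chromosome I (8584 bp), a peak on chromosome V at 6222213 to 6230407 (8195 bp, q-value 8.52e-117, rank 11) and the peak ranked 6 on chromosome II (7715 bp). Of the 22 peaks wider than 4 kb, 7 lay on X, 4 each on I, IV and V, 2 on II and 1 on III. The weakest q-value of these 22 peaks was 1.06e-23, and 14 of them were among the 53 strongest peaks of the list. On X, the peaks at 6735372 to 6740536 and at 6740826 to 6744942 lay within 500 bp of each other. Merged into 1 they would be wider than the widest listed peak, so both the count for X and the 3 widest depend on how regions were split. Across all peaks, width rose with strength. Spearman's coefficient between width and the negative log10 of the q-value was 0.558 and Pearson's was 0.625 (two-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give, n = 5338 peaks). Within single chromosomes Spearman's coefficient lay between 0.491 on X and 0.617 on IV. Peaks of 1 list are not independent replicates, and a wider region also holds more reads to test.

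**Figure D1:**
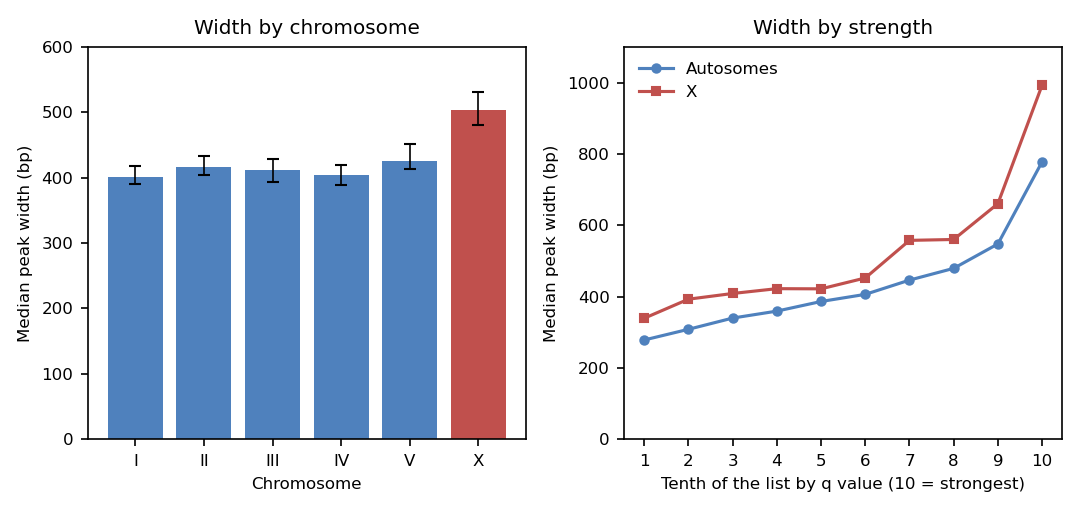
Left, median peak width in bp for each chromosome, with bars for the 95% order-statistic interval over its peaks, and right, median width in bp on X (squares) and on autosomes (circles) in each of 10 equal classes of the list by q-value, from the weakest (1) to the strongest (10). The median of X was 503.5 bp and those of the autosomes lay between 401 and 426 bp.

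Peaks on X were wider than those on the autosomes. The median width was 503.5 bp on X (834 peaks, 95% interval 480 to 531 bp) and 413 bp on the autosomes (4504 peaks), a ratio of 1.22 with a 95% block bootstrap interval of 1.15 to 1.29. A two-sided permutation of 100 kb blocks between chromosomes gave p = 0.0001, the smallest that 10000 draws can give. Among the autosomes, medians ran from 401 bp on chromosome I to 426 bp on chromosome V. Set in the same way against all other chromosomes, X included, peaks were narrower on I (ratio 0.935, permutation p = 0.0086, adjusted 0.0258) and on IV (ratio 0.944, permutation p = 0.0181, adjusted 0.0362), while II, III and V did not pass (adjusted permutation p between 0.281 and 0.775) and X had an adjusted permutation p of 0.0006. These tests were added after the widths had been seen, and X is a single chromosome.

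Peak density differed between chromosomes. It was highest on chromosome I, with 950 peaks or 63.1 per Mb, and on chromosome III, with 849 peaks or 61.6 per Mb. Chromosomes II and IV held 56.5 and 55.6 per Mb. X held 834 peaks or 47.2 per Mb, and chromosome V was the sparsest with 872 peaks or 41.7 per Mb. Set against all other chromosomes together, the ratio of densities was 0.740 for V, 1.22 for I and 1.19 for III. In the permutation of 100 kb blocks, the Benjamini-Hochberg adjusted p was 0.0006 for V, 0.0027 for I and 0.0134 for III, while II (adjusted p = 0.303) and IV (adjusted p = 0.37) did not pass. With 1 Mb blocks, chosen after seeing the data, V alone passed (adjusted permutation p = 0.006), and I had an adjusted permutation p of 0.124.

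The planned comparison was that of X with the autosomes. X held 15.6% of the peaks (exact binomial 95% interval 14.7% to 16.6%) on 17.7% of the length. Its density of 47.2 peaks per Mb was 0.863 times the 54.6 per Mb of the autosomes (two-sided exact binomial p = 8.42e-05, permutation of 100 kb blocks p = 0.0114). In a permutation of 1 Mb blocks the difference was not larger than the spread between stretches of that length (p = 0.126), and without chromosome I the 100 kb permutation p was 0.0599. Without chromosome V, the sparsest, the ratio was 0.799 (permutation p = 0.0002 with 100 kb blocks and 0.0079 with 1 Mb blocks). In the stronger 50% of the list the ratio was 0.918 (exact binomial p = 0.104), and in the strongest 25% it was 0.803 (exact binomial p = 0.00406).

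**Figure D2:**
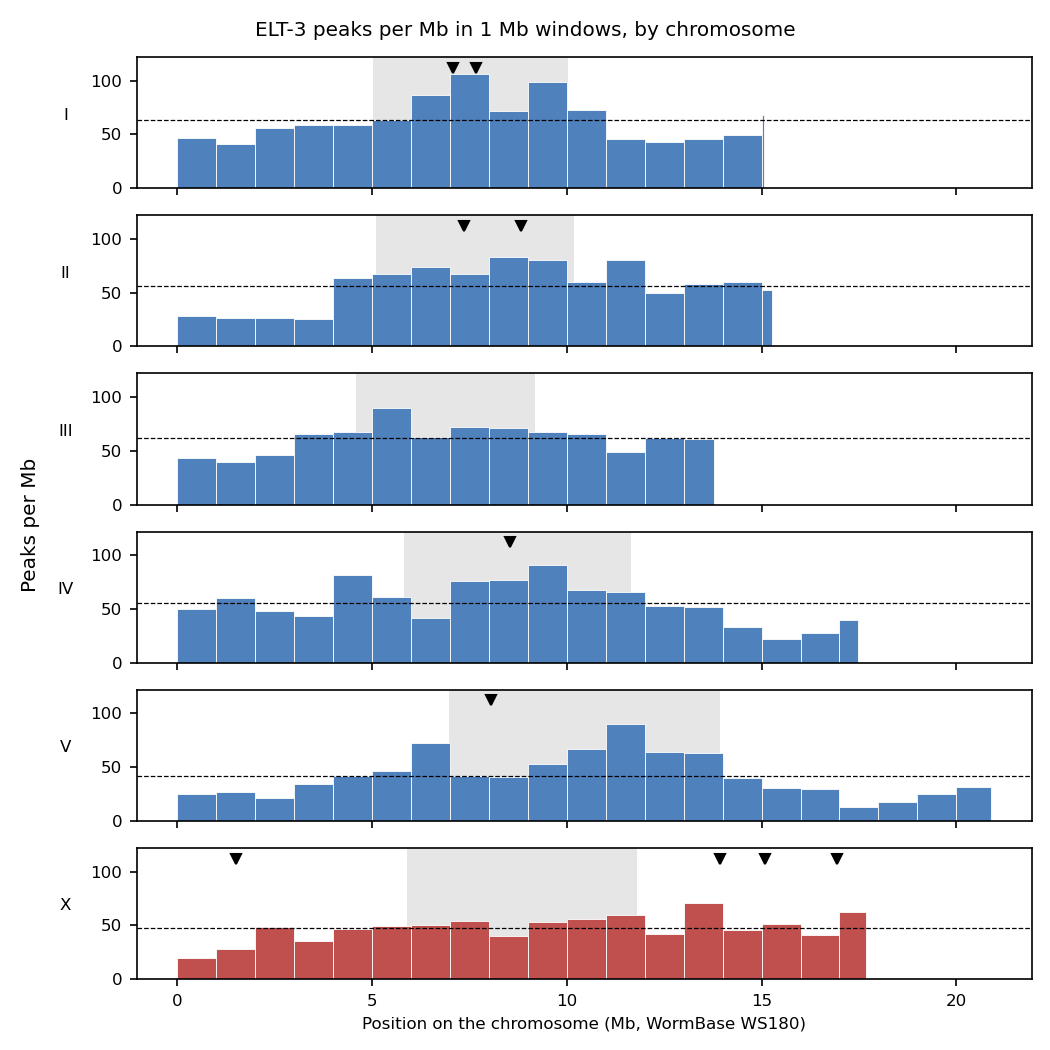
Peaks per Mb (vertical axis) in 1 Mb windows along each chromosome (horizontal axis, Mb in WS180 coordinates), with autosomes in blue and X in red, where the last window of a chromosome is shorter, the grey band marks the middle 33.3% of the length, the dashed line the mean density of the chromosome and the triangles the 10 strongest peaks. The windows of V and I are fullest inside the grey band, where 47.9% and 44.8% of their peaks lay, against 36.6% on X.

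Autosomal peaks were concentrated in the central part of the chromosomes relative to its length. Gene density differs between the central and outer parts of C. elegans autosomes, and it was not taken into account here or for X. The shares therefore do not separate a preference of ELT-3 from the layout of the genes. The middle 33.3% of the autosomes held 1951 of 4504 peaks, or 43.3% (exact binomial 95% interval 41.9% to 44.8%, exact p = 4.23e-44, block bootstrap interval 41.3% to 45.3%), which is 71.0 peaks per Mb against 46.4 per Mb in the outer parts. The central share was largest on chromosome V, with 47.9%, followed by I with 44.8%, II with 43.7%, IV with 41.8% and III with 38.2%. Each of these shares exceeded 33.3% (adjusted exact binomial p between 3.21e-18 for V and 0.00381 for III), and the block bootstrap interval of III, the closest, was 33.7% to 42.7%. The fullest complete 1 Mb window was on chromosome I from 7 to 8 Mb, with 106 peaks, and the emptiest was on chromosome V from 17 to 18 Mb, with 13 peaks. The median complete window held 52 peaks. Chromosome II was uneven along its length, with 33 peaks in the second of 10 equal parts and 118 in the fifth.

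On X the central share was the lowest of the 6 chromosomes, close to the 38.2% of chromosome III. The middle 33.3% of X held 305 of 834 peaks, or 36.6% (exact binomial p = 0.0515, block bootstrap interval 32.3% to 40.8%), which did not pass the test. It passed in the middle 50% of X, with 54.3% of the peaks (exact binomial p = 0.0139), and when the length ran from the first to the last peak, with 36.7% (exact binomial p = 0.0433), the latter chosen after seeing the data. The exact test treats neighbouring peaks as independent, and no block bootstrap interval is given for either setting. Neither pass therefore establishes a central excess on X. The central share of the autosomes exceeded that of X by 6.75 percentage points (block bootstrap interval 2.05 to 11.3, two-sided Fisher's exact p = 0.000287), a comparison added after seeing the data. The share of chromosome III (block bootstrap interval 33.7% to 42.7%) lay inside the interval of X. Those of I, II, IV and V lay above it, from 41.8% on IV to 47.9% on V. The comparison pooled the autosomes, and X is a single chromosome. A difference between X and autosomes as a class was therefore not established. Of 10 equal parts of X the eighth was the fullest, with 107 peaks, and the first the emptiest, with 48 peaks.

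More peaks had a neighbour within 2000 bp than random placement would give. Another peak midpoint lay within 2000 bp for 36.7% of the peaks, against 14.9% ± 0.633 (SD over 1000 random placements) with the number of peaks per chromosome kept, a ratio of 2.46. No placement reached more than 17.1% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). When the number of peaks in each 1 Mb window was kept, the random share was 16.13%. In the stronger 50% of the list the share was 26.4% against 6.87% at random, a ratio of 3.84, and in the strongest 25% it was 17.2% against 3.04%, a ratio of 5.67. Once peaks within 500 bp were merged into 1, the share fell to 25.2% against 13.2% at random, a ratio of 1.91. The placements of merged peaks allowed gaps of 500 bp or less, which the merged list cannot hold. This raises their random share, so the lower ratio does not show weaker clustering. The excess was seen from 1000 bp, where 11.3% of the peaks had a neighbour against 5.21% at random, to 20000 bp, where 90.1% had one against 88.1%. At 500 bp the list lay below both kinds of placement, with 0.112% against 95% ranges of 0.524% to 1.16% per chromosome and 0.599% to 1.39% per 1 Mb window. At 30000 bp (95.1%) and 50000 bp (98.8%) it lay below the range of the placements per chromosome (95.4% to 96.4% and 99.3% to 99.6%) and inside that of the placements per 1 Mb window (94.8% to 95.8% and 98.7% to 99.3%). No neighbouring peaks overlapped and the smallest gap in the list was 200 bp. The placements behind these ranges allowed smaller gaps, so the low share at 500 bp cannot be told apart from this limit of the list.

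**Figure D3:**
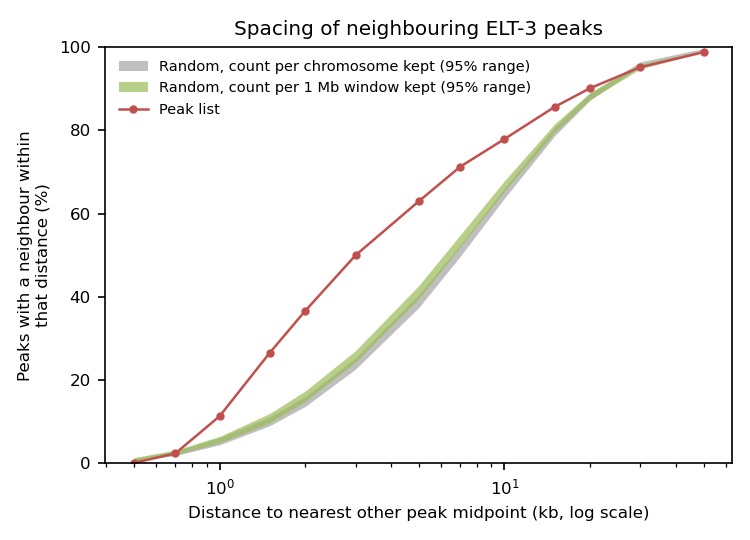
Share of peaks in percent (vertical axis) with another peak midpoint within a given distance (horizontal axis, kb, log scale) in the list (red) and in 200 random placements that keep the number of peaks per chromosome (grey, 95% range) or per 1 Mb window (green, 95% range). The list lies above both ranges from 1 to 20 kb and reaches 62.9% at 5 kb, against 39.0% and 41.2% in the placements.

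The stretch of 20 kb with the most peaks was on chromosome IV, from 4014124 to 4033878, and held 14 peaks that covered 7.48 kb of its 19.8 kb. The strongest of these peaks lay at 4030820 to 4031436 (617 bp, q-value 5.39e-43, rank 106), followed by those at 4023947 to 4025120 (1174 bp, q-value 8.42e-23, rank 394) and at 4028057 to 4029057 (1001 bp, q-value 1.07e-12). The peak at 4029269 to 4029824 had a q-value of 7.55e-11. The other 10 peaks of the stretch were weaker than 1e-10, down to 0.00961 for a peak of 68 bp at 4017079 to 4017146.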

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

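The 1 Mb blocks, the lengths from first to last peak, the 200 bp gap and 1 Mb placements, Pearson's coefficient without the 100 strongest peaks, and the tests of width by chromosome, narrow peaks and neighbour strength were chosen after seeing the data. No paired analysis was possible because the list holds no value per library, and for the same reason no replicate could be left out. The clustering of neighbours, the central share on autosomes and the relation of width to q-value kept their direction and their side of 0.05 in each of 13, 10 and 4 alternatives. The density ratio of X to autosomes stayed below 1 in 11 alternatives, from 0.799 without chromosome V to 0.918 in the stronger 50% of the list, where it did not pass (exact binomial p = 0.104). At the main ratio of 0.863 it did not pass either in a permutation of 1 Mb blocks (p = 0.126), and the cause of neither change was tested. The median width was 530 bp in the stronger 50% of the list and 431 bp after merging peaks within 500 bp, against 424 bp. The central share of X, 36.6%, passed the exact binomial test when the middle 50% was taken (54.3%, p = 0.0139) or when lengths ran from the first to the last peak (36.7%, p = 0.0433). That test treats neighbouring peaks as independent, and no block bootstrap interval is given for either setting. The wider peaks of X (10 alternatives) and the narrow peaks of IV (4 alternatives) kept their direction and call. The higher strength of peaks with a neighbour was not seen at 1000 bp, where the difference in median negative log10 q-value was -0.286 (permutation p = 0.220). The cause of this change was not tested. Other settings for peak position relative to genes, gene lists and the GATA motif were not run, because the gene table is of another build. Chromosome lengths were taken from the last peaks, and neither the depth nor the detection limit of the list is known.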

Other observations

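All tests in this part were chosen after the list had been seen. The bounds for the classes by q-value on X, for the peaks of IV left after joining within 500 bp and for the windows of IV with narrow peaks were set after their values had been seen as well, and the bounds of the others before.

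Of the 10 strongest ELT-3 peaks, 6 of 6 on autosomes and 0 of 4 on X lay in the middle 33.3% of their chromosome. These 10 peaks prompted the question, so they were left out of its test. Among the peaks ranked 11 to 100, 48 of 77 on autosomes (62.3%) and 5 of 13 on X (38.5%) lay there (two-sided Fisher's exact p = 0.133), and among those ranked 11 to 500 the shares were 52.8% of 415 and 42.7% of 75 (Fisher's exact p = 0.132). Ranks 11 to 50 gave a Fisher's exact p of 0.265 and ranks 11 to 200 gave 0.023, so 1 of 4 overlapping sets passed 0.05 without adjustment, and a difference in the place of the strongest peaks was not established.

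Peaks with another midpoint within 2000 bp were stronger than the rest, with a median q-value of 1.62e-06 for 1957 peaks against 1.34e-05 for 3381 peaks (permutation within chromosomes p = 0.0001, the smallest that 10000 draws can give). The difference in median negative log10 q-value was 0.917 there, with the same p when q-values were permuted within 1 Mb windows, and it was -0.286 (permutation p = 0.220) for a distance of 1000 bp. Weak regions split off the flanks of strong peaks were to be excluded as its source by a difference of at least 0.5 among peaks without another edge within 500 bp, a bound set in advance. The difference there was 0.525 (permutation p = 0.0017), above the bound, and was first read as excluding them. That reading was withdrawn after the result had been seen, because the difference lies above the bound by less than its spread (block bootstrap interval 0.204 to 0.979), and the question is left open.

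The wider peaks on X were weighed against 3 technical explanations. If X peaks were wider only through other q-values, no difference would be left at a given q-value. The median on X was nevertheless the larger in 10 of 10 equal classes of the list by q-value, with ratios from 1.09 to 1.28. Because the q-value itself rises with width, these classes cannot test a difference in read signal per bp. More frequent joining of neighbouring regions on X was argued against by a ratio of 1.24 (block bootstrap interval 1.16 to 1.31) once all peaks within 1000 bp had been joined on every chromosome. Less room between autosomal peaks was argued against by a ratio of 1.196 (interval 1.096 to 1.328) among peaks with no other edge within 5000 bp. A caller threshold or background that differs between chromosomes stays open, since the list holds no read counts, and no biological explanation was tested.

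Very narrow peaks were unevenly spread, since of 125 peaks under 100 bp 46 lay on chromosome IV, or 4.74% of its 971 peaks, against 1.81% of the peaks elsewhere (two-sided Fisher's exact adjusted p = 4.64e-06, block permutation adjusted p = 0.0006), and 6 lay on X, or 0.719% of its peaks (Fisher's exact adjusted p = 0.000742), and all were weak, with a median q-value of 0.00427 and none stronger than 2.64e-05. Weaker q-values on IV would be a candidate explanation, but within 10 equal classes of the list by q-value the odds ratio for IV was 2.86 (block bootstrap interval 1.98 to 4.21). As for X, such classes cannot test a difference in read signal per bp. An origin in a few places on IV is argued against as well, since such peaks occurred in 15 of its 18 windows of 1 Mb. What stays open, as a hypothesis, is that the calling differed between chromosomes, which may bear on the widths of X too, although among peaks of at least 200 bp the ratio of median widths of X to autosomes was 1.201. No biological explanation was tested.

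The run of 14 peaks in 20 kb on chromosome IV was denser than the uneven density along the chromosome at the 1 Mb scale would give. Placements that kept the number of peaks in each 1 Mb window held at most 11 peaks in any 20 kb (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Such placements do not keep the clustering of neighbours seen across the list, where 36.7% of the peaks had a neighbour within 2000 bp against 16.13% in them. They thus cannot show that this stretch is denser than that clustering would give. A single wide stretch split by gaps of up to 500 bp is argued against, because 10 peaks were left after joining those within 500 bp. Several of the gaps that remained were under 1000 bp, and joining over wider gaps was not tested for this stretch. Splitting by such gaps therefore stays open. Once peaks were joined in this way on every chromosome, the stretch no longer exceeded the highest count in placements of the joined peaks, which was 10, although only 6 of 1000 placements reached it (one-sided permutation p = 0.00699). Extra copies of this stretch in the strain, or a sequence to which reads from elsewhere align, may also give such a run and were not tested, as the list holds no input signal, nor was any biological explanation.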
